A study of Homo sapiens with 24 samples.

How the data were processed

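Messenger RNA was measured in 24 libraries of the EGFR-mutant lung cancer lines PC9 and HCC4006, 12 per line. Per the labels, cells were control (CTRL) or YAP1 knockout (YAP1 KO), were grown in 10 cm dishes in triplicate and were treated for 24 hours with DMSO or with osimertinib at 100 nM plus trametinib at 30 nM (OT). RNA was extracted with TRIzol and libraries were made with a stranded mRNA kit, per the labels' protocols. The authors deposited 1 table of FPKM (fragments per kilobase of transcript, scaled by the mapped fragments), with 1 column per library and 25365 gene rows named by symbol. The submitters' processing notes name STAR 2.5.1b, Cufflinks 2.2.1 and DESeq2 1.10.1, without a role or order, and the builds hg19 and GRCh37. The annotation is not given in the sources used here, and DESeq2 output was not analysed here. No coordinates were used. Symbols in 28 rows were date-like, and these rows were kept but are not named. Each library was assigned to its group from its labels, and all per-sample columns were mapped.

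FPKM are not counts, so no count model was used. The FPKM of a library summed to 507120 to 660459, and 2.43% to 8.13% of the sum lay in the rows of MIR1244-1 and MIR1244-2. Both the sum and that share were lower in every OT library than in any DMSO library of its line. Absolute depth is unknown. Relative depth was estimated from the steps that 1 read makes in genes with FPKM under 0.5, and ran from 0.945 to 1.42. Comparisons were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), so a fold change understates the change of low genes. For each line the 4 groups of 3 were fitted together in 1 model with group means and no other term, and with empirical Bayes moderation that follows the trend of the spread with intensity. Genes were kept with FPKM of at least 1 in at least 3 of the 12 libraries, which left 12685 in PC9, 13113 in HCC4006 and 11845 in both. The median residual SD was 0.0696 in PC9 and 0.0896 in HCC4006 on the log2 scale, with 8 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and counts of genes changed at least 2-fold also needed a log2 change of 1 or more in size. The 5 comparisons made per line were OT against DMSO in CTRL and in YAP1 KO cells, YAP1 KO against CTRL under DMSO and under OT, and the interaction of genotype and treatment, which is the OT response in YAP1 KO cells minus that in CTRL cells.

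Differences between lines were tested in 1 fit of the 24 libraries and 8 groups, and also against a difference of 1 on the log2 scale (limma treat). Overlaps of the lines were set beside the number that independent lists of the same sizes would share. Genes that changed at least 2-fold with OT in CTRL cells of one line were tested as a set in the other line. Gene lists, 32 with 651 members of which 638 had a row, were tested with limma's fry, adjusted over the lists and 5 comparisons of a line. Fry asks whether the genes of a list move, on balance, one way, and does not compare the list with other genes. The limma test camera, with the correlation between genes estimated within each list, was the alternative and compares a list with the other genes. The list of mitochondrially encoded transcripts was not analysed here.

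Named genes followed a rule. It took YAP1, the 5 highest and 5 lowest genes called the same way in both lines (ranked by the smaller change), the 3 highest and 3 lowest per line, and up to 4 members per list with the largest mean change over the lines among members called in at least 1 line. It also took BMF, BCL2L11, SNAI2, CTGF, CYR61, ANKRD1, DUSP6, SPRY4, CCND1, MKI67, CDKN1A, WWTR1, TEAD1, EGFR and AXL whatever their result. The text names about 20 to 30 of these genes per comparison and leaves out rows of short RNAs, except 2 named after their values were seen. Some genes that the rule took are not reported here. The groups, tests, gene lists, named-gene rule and most alternatives were fixed before the data were examined.

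The tests were tried on simulated data with 200 changed genes, 100 at each of 2 sizes. At a log2 change of 0.5 the OT comparison in CTRL cells recovered 98% of them in PC9 and 91% in HCC4006, and the interaction 84% and 57%. At a log2 change of 1 the shares were 98%, 97%, 97% and 95%. The difference between lines for OT recovered 79% and 98% at the 2 sizes. Unchanged genes made up 7.11% and 5.53% of the calls for OT in PC9 and HCC4006, 4.74% and 3.80% for the interaction, and 5.85% for the difference between lines. Of 100 random lists, fry called 6 in PC9 and 4 in HCC4006 and camera 2 and 0, at an unadjusted p under 0.05. The simulated noise was independent between genes, so this does not show how fry behaves where genes of a list are correlated. Changed genes were drawn above a minimum mean level, so the recovered shares do not cover low genes.

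Alternatives were pseudocounts of 0.1 and 0.01, no filter on low values, a filter at FPKM of 5, 3 other scalings (median-of-ratios, each library rescaled to the same sum, as in TPM, and quantile normalization), robust empirical Bayes, fits of only the 2 groups compared, the replicate number as a block, and leaving out each library in turn. Leaving out libraries for results that compare the lines, and leaving out rows of short RNAs, were added after seeing the data. Replicate numbers in the labels were taken to pair libraries where deviations from the group means correlated at over 0.1 in all 3 pairs of the groups compared. Only HCC4006 CTRL cells under DMSO and OT met this (0.134, 0.146 and 0.143), and the pairing there comes from the values, not from a label. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.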

Results

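The data were collected to ask what loss of YAP1, the transcriptional coactivator at the end of the Hippo pathway, does to the transcriptional response of lung cancer cells to combined EGFR and MEK inhibition, including genes of the apoptotic pathway. PC9 (PC-9) and HCC4006 are established lung adenocarcinoma lines that carry an activating EGFR mutation. Each line was studied as control cells (CTRL) and as cells labelled YAP1 knockout (YAP1 KO), after 24 hours in DMSO, the solvent, or in OT. OT is the EGFR inhibitor osimertinib at 100 nM together with the MEK inhibitor trametinib at 30 nM. The 2 lines, 2 genotypes and 2 treatments made 8 groups of 3 dishes, and each dish gave 1 mRNA sequencing library, so 24 libraries were compared. The dishes of a line came from the same cell populations, with 1 YAP1 KO population per line, so p-values here measure the spread between dishes. Levels were the authors' FPKM (fragments per kilobase of transcript, scaled by the mapped fragments), which summed to 507120 to 660459 per library over 25365 gene rows. The absolute depth is unknown. From the steps that 1 read makes in low genes, relative depth ran from 0.945 to 1.42 times that of the first PC9 CTRL DMSO library, and the deepest was replicate 1 of HCC4006 CTRL OT. Libraries of a group correlated across genes at r of 0.976 to 0.987 in HCC4006 and 0.982 to 0.987 in PC9. Cell line and treatment separated the libraries along the first pair of principal components.

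**Figure D1:**
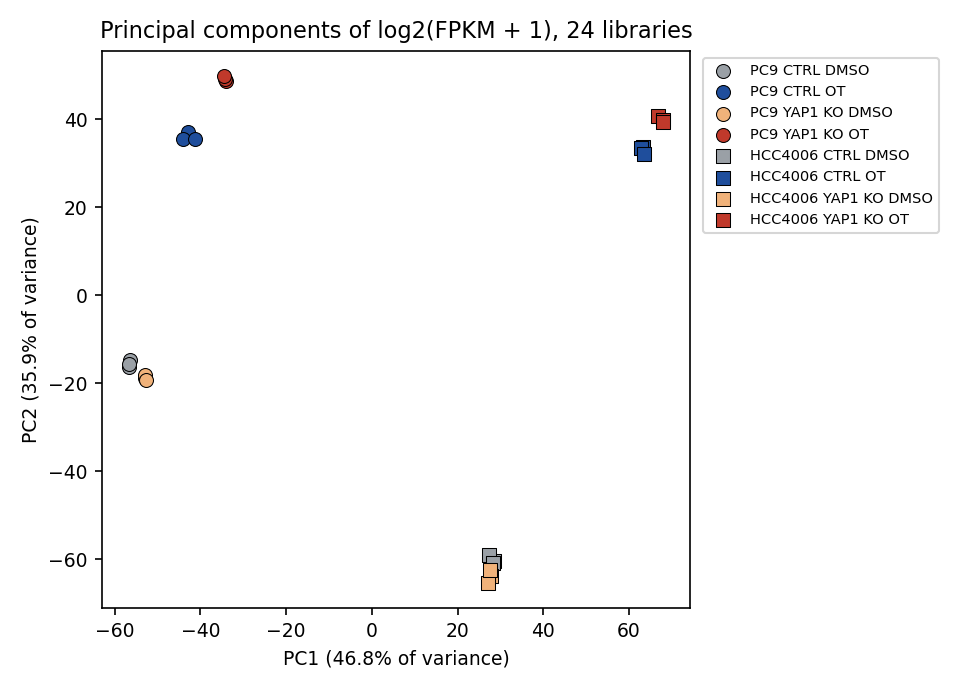
Principal components of log2(FPKM + 1) for the 24 libraries, with PC9 as circles, HCC4006 as squares and colours for genotype and treatment. PC1 held 46.8% and PC2 35.9% of the variance, and the 3 libraries of each group lie close together.

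YAP1 was lower in every library labelled YAP1 KO than in any CTRL library of its line. In PC9 its level was 42.9 ± 0.415 FPKM (SD, n = 3) in CTRL cells under DMSO and 12.1 ± 0.398 in YAP1 KO cells, 28.1% of the control level. Under OT the PC9 levels were 34.2 ± 0.371 and 11.01 ± 0.841, or 32.2%. HCC4006 had 18.2 ± 1.62 FPKM in CTRL cells under DMSO and 4.24 ± 0.344 in YAP1 KO cells (23.2%), and 15.5 ± 1.51 against 6.13 ± 0.190 under OT (39.6%). On the log2(FPKM + 1) scale the YAP1 KO difference was -1.75 in PC9 and -1.88 in HCC4006 under DMSO (adjusted p = 3.36e-10 and 4.26e-08), and -1.55 and -1.20 under OT (adjusted p = 3.89e-10 and 2.99e-07). The table holds 1 value per gene, so it does not show which part of the transcript the remaining fragments came from, nor whether protein was made.

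**Figure D2:**
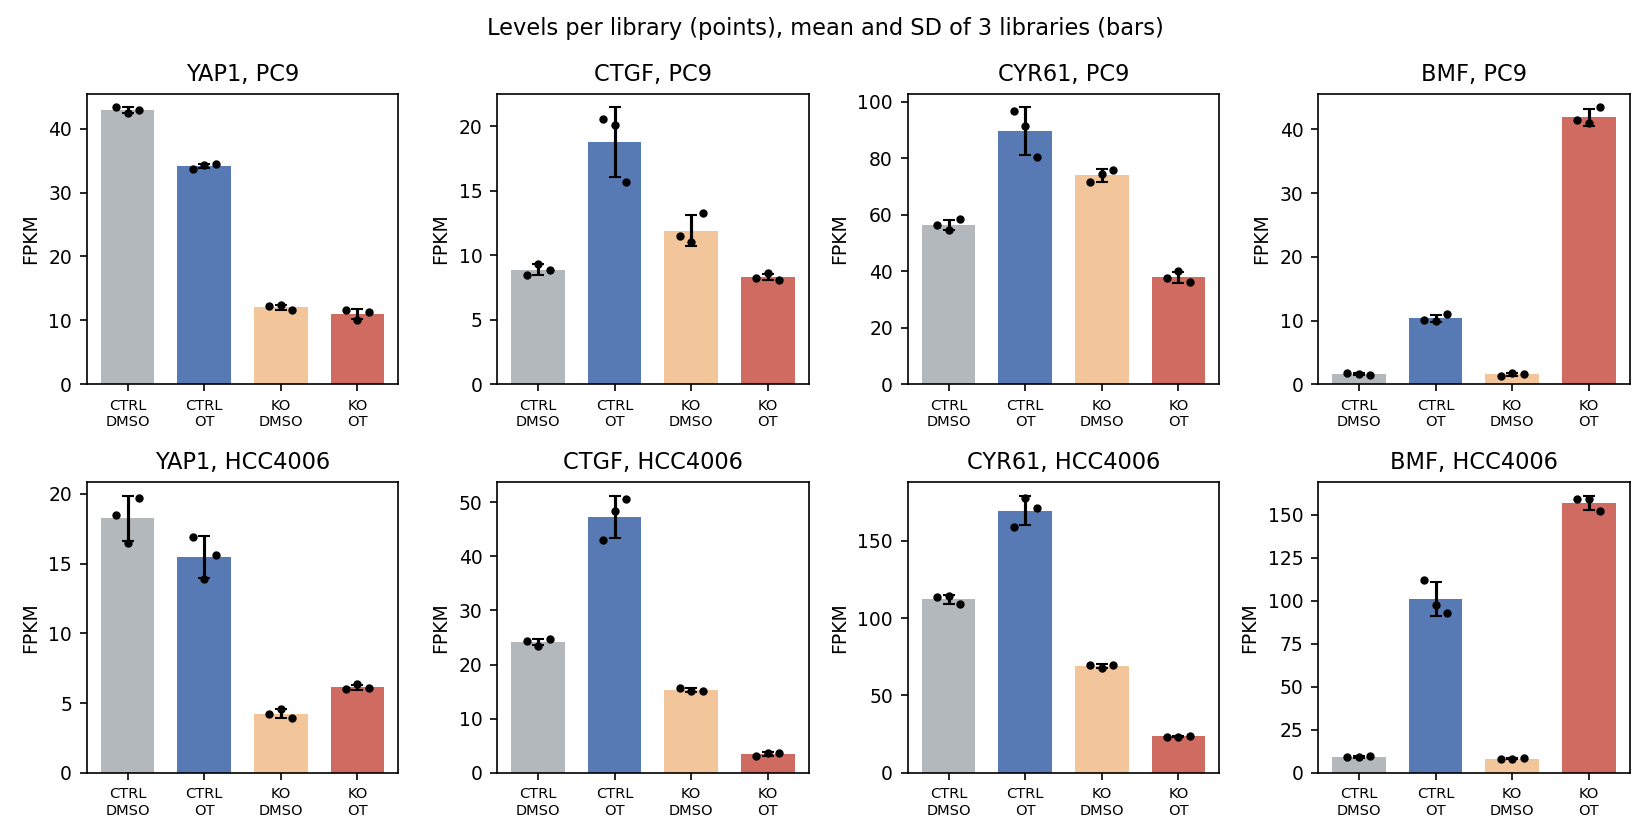
FPKM of YAP1, CTGF, CYR61 and BMF in each library (points), with the mean (bars) and SD (error bars) of the 3 libraries of a group, for PC9 in the upper panels and HCC4006 in the lower ones. In both lines the mean of BMF was highest in YAP1 KO cells under OT and those of CTGF and CYR61 were lowest there, although for CTGF in PC9 the 8.31 ± 0.262 FPKM of that group lay close to the 8.88 ± 0.424 of CTRL cells under DMSO.

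The first comparison asked what OT did to control cells. Genes of the MAPK pathway and of proliferation fell together in both lines, while genes of quiescence, lysosomes and interferon signalling mostly rose. Among outputs of MAPK signalling, 17 of 18 measured genes fell and 1 rose in PC9, and 19 of 19 fell in HCC4006. The phosphatase DUSP6 changed by -2.44 in PC9 and -5.37 in HCC4006 (log2, here and for the other genes), the transcription factor ETV4 by -3.65 and -3.26, the AP-1 subunit FOSL1 by -3.17 and -3.47, and PHLDA1 by -2.82 and -4.55. The feedback inhibitor SPRY4 fell too (-1.53 and -1.92), as did cyclin D1, CCND1 (-1.22 and -3.69). All 30 S-phase genes and all 30 G2/M genes fell in each line, among them the replication licensing factor CDC6 (-2.32 and -3.95), CDK1 (-1.65 and -4.58) and the proliferation marker MKI67 (-1.10 and -2.94). Ribosome biogenesis genes fell in 28 of 28 and 27 of 28 cases, with NOP56 at -1.41 and -1.83. Set tests with fry gave an adjusted p of 2.28e-10 or lower for each of these lists in either line. Values given with an estimated correlation, here and below, are from camera. It answers another question, whether a list moved differently from the other genes. By camera the adjusted p was 0.0121 for MAPK output, 0.0186 for S-phase genes, 0.0194 for G2/M genes and 0.0186 for ribosome biogenesis in PC9. In HCC4006 it was 0.0149 for S-phase genes and 0.0104 for ribosome biogenesis, while MAPK output (adjusted p = 0.111 with an estimated correlation) and G2/M genes (adjusted p = 0.106) did not pass camera.

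Among cell cycle inhibitors and quiescence genes, 15 of 22 rose in PC9 and 15 of 20 in HCC4006, including the antiproliferative BTG2 (1.40 and 1.85) and the MAX partner MXD4 (1.23 and 2.25). Lysosome and autophagy genes rose in 21 of 27 and 18 of 27 cases, led by GABARAPL1 (2.05 and 2.40), and type I interferon response genes in 18 of 26 and 25 of 30, with STAT2 at 1.14 and 1.81. Epithelial junction and keratin genes rose in 17 of 24 cases in each line, with the epithelial transcription factor ELF3 at 1.85 and 1.96. None of these 4 lists passed camera, with an estimated correlation (adjusted p = 0.0743, 0.0696, 0.0668 and 0.0687 in PC9, and 0.235, 0.142, 0.0933 and 0.304 in HCC4006). With rows of short RNAs set aside, the highest changes shared by the lines were in C10orf10 (3.08 and 3.51), the PI3K-binding PIK3IP1 (2.78 and 3.52) and the immune checkpoint ligand VTCN1 (2.82 and 5.41).

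Genes of the YAP/TEAD target signature mostly rose with OT: 15 of 22 were higher and 6 lower in PC9, and 13 of 21 were higher and 6 lower in HCC4006 (adjusted p = 0.213 and 0.514 with an estimated correlation). The matricellular genes CTGF and CYR61 rose by 0.99 and 0.65 in PC9 and by 0.94 and 0.59 in HCC4006, and CCDC80 by 2.19 and 2.78. Members moved apart, however: NT5E changed by -0.84 and -3.98, and ANKRD1 by -2.00 in PC9 and 1.49 in HCC4006. Of 10 measured pro-apoptotic BCL2 family genes, 4 rose and 3 fell in PC9, and 4 rose and 2 fell in HCC4006 (adjusted p = 0.622 and 0.511 with an estimated correlation). In PC9 the median of this list was -0.04 although the set test pointed up. BMF, a BH3-only protein that promotes apoptosis, rose from 1.67 ± 0.159 to 10.4 ± 0.538 FPKM in PC9 (log2 2.09, SE 0.069, adjusted p = 9.21e-11) and from 9.12 ± 0.345 to 101 ± 9.86 in HCC4006 (3.33, SE 0.064, adjusted p = 6.08e-13). The BH3-only genes BCL2L11, which encodes BIM, and BBC3, which encodes PUMA, rose by 0.87 and 0.88 in PC9 and by 1.20 and 2.57 in HCC4006. BCL2L1, which encodes the survival protein BCL-XL, changed by -0.87 and -0.78. EGFR itself changed by -0.06 (adjusted p = 0.397) in PC9 and -0.15 (adjusted p = 0.429) in HCC4006, and without replicate 1 of HCC4006 CTRL OT the second value was -0.43 (adjusted p = 1.44e-05).

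Of cholesterol biosynthesis genes, 13 of 23 rose and 2 fell in PC9 (adjusted p = 0.384 with an estimated correlation), and 22 of 24 fell and 1 rose in HCC4006 (adjusted p = 0.0116 with an estimated correlation), and the list was not tested for a difference between the lines. The sterol demethylase gene MSMO1 changed by 0.64 in PC9 and -1.62 in HCC4006, a difference beyond 1 on the log2 scale (adjusted p = 7.31e-11). TM7SF2 rose in both (1.87 and 2.62). Glycolysis genes fell in 17 of 23 and 18 of 22 cases (adjusted p = 0.249 and 0.201 with an estimated correlation), with LDHA at -0.69 and -1.93. The receptor gene MET changed by 0.68 in PC9 and -2.27 in HCC4006 (adjusted p = 1.13e-14 for a difference beyond 1).

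By the limma test with Benjamini-Hochberg adjustment, 4064 genes were higher and 5192 lower with OT among 12685 tested in PC9 CTRL cells, of which 416 and 583 changed at least 2-fold. That majority depended on the scaling, with 4732 higher and 4593 lower (50.7% in place of 43.9%) by median-of-ratios and 4610 and 4611 with each library rescaled to the same sum. Median-of-ratios scaling moves the median change towards 0 by design, here to 0.0132 from -0.0448. It thus pulls splits towards even, here and below, and cannot show which direction prevailed. HCC4006 CTRL cells had 5896 higher and 4804 lower among 13113, with 1562 and 1277 at least 2-fold. When each library was rescaled to the same sum, the HCC4006 split was 7070 higher to 3597 lower, a share of 66.3% in place of 55.1%, with 2611 and 1037 at least 2-fold, and the median change of all genes moved from 0.09 to 0.30. Median-of-ratios scaling gave 5442 higher and 5289 lower there (50.7%), and the 2-fold majority turned, to 1387 and 1454. At a pseudocount of 0.1 the 2-fold counts were 743 and 928 in PC9 and 2417 and 1604 in HCC4006. Adjusted over the list alone, counts were the same for the lists named in this comparison, except 19 higher for interferon genes and 5 lower for lysosome genes in PC9. Rows of short RNAs supplied 14 of the 20 largest changes in PC9 and 6 of 20 in HCC4006, and are left unnamed because their residual SD was 22.1 and 18.4 times (median) that of other rows of the same mean.

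**Figure D3:**
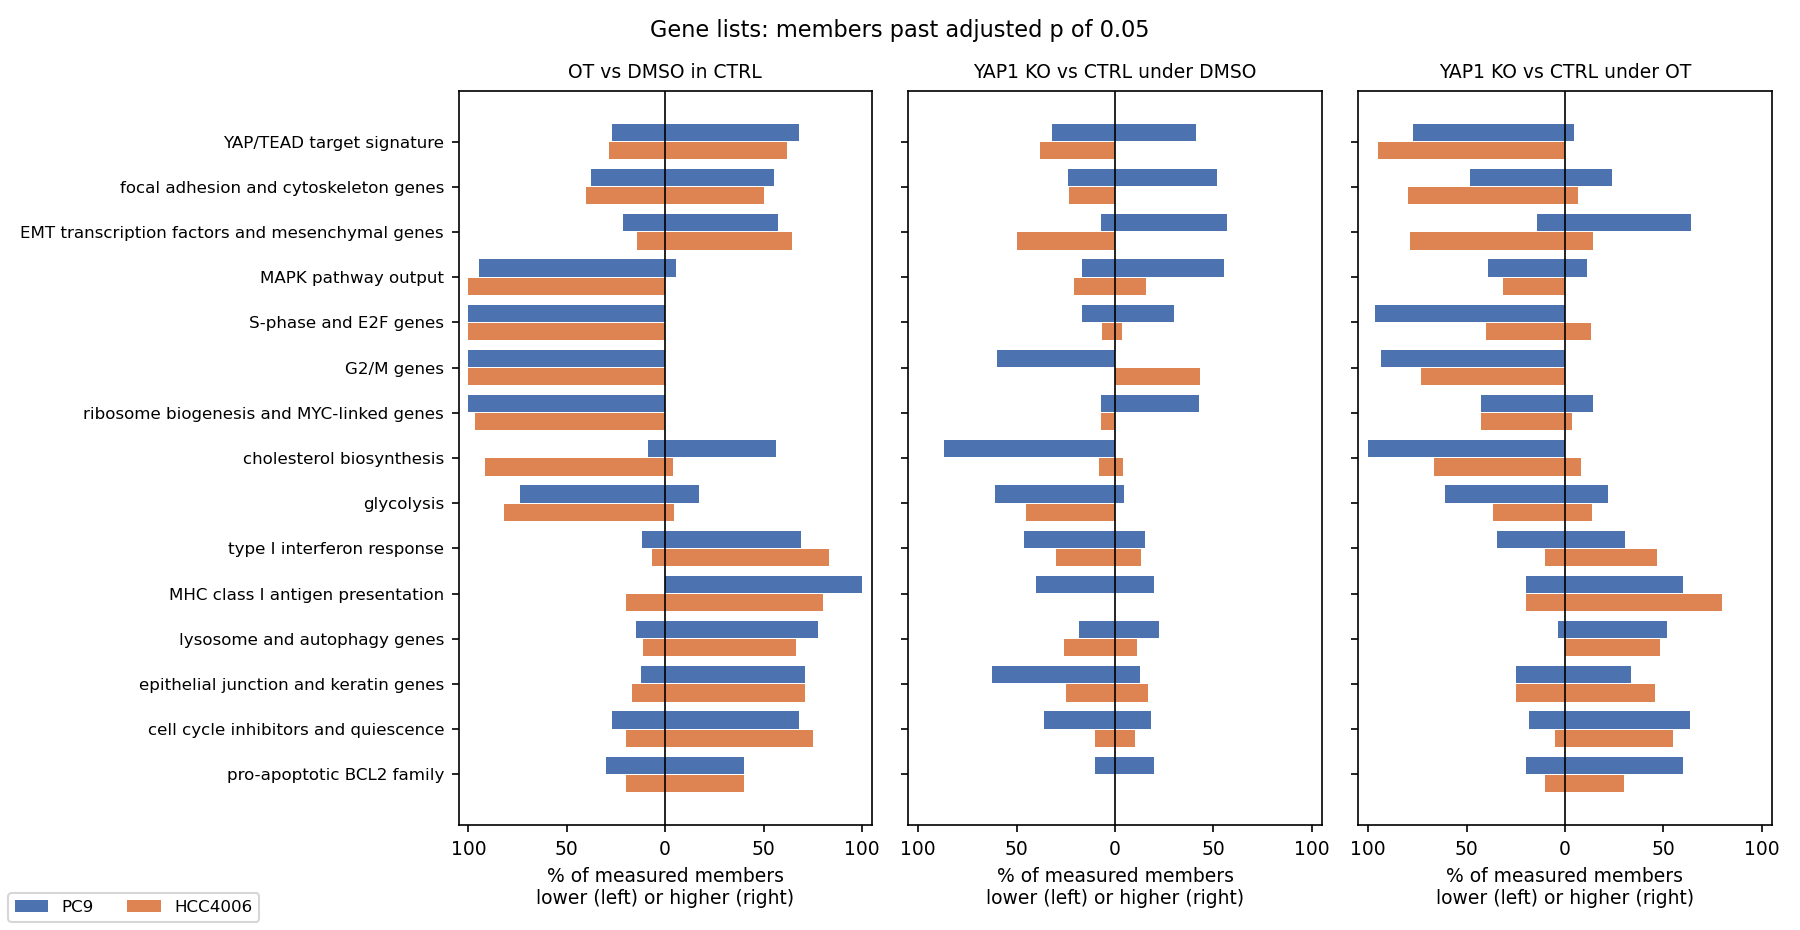
Share of each gene list's measured members past an adjusted p of 0.05, lower to the left and higher to the right, for PC9 (blue) and HCC4006 (orange) in 3 comparisons. All 30 S-phase and all 30 G2/M genes fell with OT in CTRL cells of both lines, and 17 of 22 (PC9) and 20 of 21 (HCC4006) YAP/TEAD target genes were lower in YAP1 KO cells under OT.

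The second comparison asked what YAP1 loss did without the inhibitors. At a pseudocount of 1 few genes changed by 2-fold or more. In PC9 the YAP/TEAD target signature went both ways, with 9 of 22 genes higher and 7 lower (fry adjusted p = 0.398), whereas in HCC4006 8 of 21 were lower and none was higher (adjusted p = 1.51e-05, and 0.0897 with an estimated correlation). CTGF and CYR61 were each 0.38 higher in PC9 YAP1 KO cells, and changed by -0.63 and -0.70 in HCC4006. CCDC80 was lower in both (-0.77 and -0.85), as was the angiomotin gene AMOTL2 (-0.49 and -0.46). Cholesterol biosynthesis genes were lower in PC9, 20 of 23 (adjusted p = 7.22e-09, and 0.0232 with an estimated correlation), with INSIG1, a regulator of sterol synthesis, at -1.80. The HCC4006 value of INSIG1 was -0.09 (adjusted p = 0.476), and 2 of 24 genes of the list fell and 1 rose there (adjusted p = 0.341 with an estimated correlation). Between the lines INSIG1 differed beyond 1 on the log2 scale (adjusted p = 0.00261).

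EMT transcription factors and mesenchymal genes were higher in PC9 YAP1 KO cells, 8 of 14 with 1 lower (adjusted p = 5.46e-08, and 0.0510 with an estimated correlation), and lower in HCC4006, 7 of 14 (adjusted p = 2.86e-09, and 0.0149 with an estimated correlation). Fibroblast markers were higher in 1 of 3 cases in PC9 and lower in 3 of 5 in HCC4006 (fry adjusted p = 0.000127 and 1.28e-07, and 0.505 and 0.0610 with an estimated correlation). The filter can admit a low marker through the 1 group where it is high, and the measured members differ. These values therefore cannot show a difference between the lines. The collagen gene COL6A2 changed by 1.48 and -0.70, and SPARC by 0.85 and -1.01, both differences beyond 1 between the lines (adjusted p = 3.98e-09 each). VIM, which encodes vimentin, was 1.80 higher in PC9, while TAGLN was lower in both (-0.71 and -1.40). G2/M genes were lower in 18 of 30 cases in PC9 and higher in 13 of 30 in HCC4006 (adjusted p = 0.143 and 0.254 with an estimated correlation), with CENPF at -0.34 and 0.56. Interferon response genes were lower in 12 of 26 and 9 of 30 cases and higher in 4 of each (adjusted p = 0.174 and 0.227 with an estimated correlation), with IFI6 at -0.83 and -0.90 and MX1 at -0.69 and -0.66. The cell cycle inhibitor CDKN1A was 0.97 higher in PC9. BMF and BCL2L11 did not pass the test: BMF had -0.05 in PC9 (adjusted p = 0.588) and -0.12 in HCC4006 (adjusted p = 0.216), and BCL2L11 had -0.11 and -0.05 (adjusted p = 0.111 and 0.741). Without replicate 3 of PC9 CTRL DMSO, BCL2L11 passed in PC9 at -0.18 (adjusted p = 0.00727).

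Higher in both lines were the TGF-beta pseudoreceptor BAMBI (0.81 and 0.64), MFAP2 (2.04 and 0.70) and SLITRK6 (0.73 and 0.70). Lower in both were ZBED2 (-0.90 and -1.35) and LINC01133 (-1.47 and -0.96). In HCC4006 alone KRT75 and the gap junction gene GJA1 were measured, at -2.64 and -2.32. Under DMSO 2517 genes were higher and 2540 lower in PC9 YAP1 KO cells (56 and 60 at least 2-fold), and 1206 and 1134 in HCC4006 (3 and 56). The HCC4006 split turned with the scaling, to 1047 and 1275 by median-of-ratios and 1284 and 837 with each library rescaled to the same sum, where 12 genes were at least 2-fold higher. The 2-fold counts rose at a pseudocount of 0.1, to 160 and 140 in PC9 and 32 and 169 in HCC4006, and at 0.01, to 174 and 150 and to 44 and 216. Without rescaling, at a pseudocount of 1, the 3 were LYPD3 (adjusted p = 1.13e-06) and the small nucleolar RNAs SNORA5A (0.0199) and SNORA60 (0.0423), named after their values were seen. The HCC4006 count of higher genes was 779 and 796 without CTRL DMSO replicate 1 or 2, and 681 and 711 without YAP1 KO DMSO replicate 1 or 2. Without YAP1 KO DMSO replicate 1, 761 genes were lower, so the majority turned there too. The count of 3 became 5, 6 and 5 without YAP1 KO DMSO replicate 2, YAP1 KO DMSO replicate 3 or YAP1 KO OT replicate 3. Adjusted over the list alone, the YAP/TEAD counts were 10 higher and 7 lower in PC9 and 1 higher and 8 lower in HCC4006, cholesterol genes 21 lower in PC9, mesenchymal genes 9 higher in PC9 and 1 higher in HCC4006, G2/M genes 19 higher in HCC4006, interferon genes 5 higher in each line, and fibroblast markers 1 lower in PC9.

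The third comparison set YAP1 KO against CTRL cells under OT. YAP/TEAD target genes were now lower in both lines, 17 of 22 with 1 higher in PC9 and 20 of 21 in HCC4006 (adjusted p = 1.38e-07 and 2.28e-10, and 0.0687 and 0.0104 with an estimated correlation). CTGF changed by -1.08 in PC9 and -3.44 in HCC4006, CYR61 by -1.22 and -2.80, the tissue factor gene F3 by -0.52 and -1.97, and TGFB2 by -0.93 and -1.61. Focal adhesion and cytoskeleton genes were lower in 14 of 29 and 24 of 30 cases and higher in 7 and 2 (adjusted p = 0.572 and 0.0528 with an estimated correlation), with the alpha-actinin gene ACTN1 at -0.36 and -1.38. The Hippo pathway genes AMOTL2 (-0.60 and -1.53) and WWC1 (-1.08 and -1.29) were lower as well, within a list of Hippo components in which 12 of 24 and 11 of 23 were lower and 4 and 2 higher (adjusted p = 0.303 and 0.325 with an estimated correlation).

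Cholesterol biosynthesis genes were lower in 23 of 23 cases in PC9 and 16 of 24, with 2 higher, in HCC4006 (adjusted p = 0.0232 and 0.0149 with an estimated correlation), with the reductase gene DHCR7 at -1.53 and -0.36. S-phase genes were lower in 29 of 30 cases in PC9 (adjusted p = 0.0186 with an estimated correlation), and in 12 of 30 with 4 higher in HCC4006 (adjusted p = 0.304). The thymidylate synthase gene TYMS changed by -1.37 and -0.83, CDC6 by -1.39 and -0.37, and CCND1 by -0.97 and -0.72. G2/M genes were lower in 28 of 30 and 22 of 30 cases (adjusted p = 0.0186 and 0.227 with an estimated correlation), with ANLN at -0.92 and -0.85. Mesenchymal genes were higher in 9 of 14 cases with 2 lower in PC9 (adjusted p = 0.163 with an estimated correlation) and lower in 11 of 14 with 2 higher in HCC4006 (adjusted p = 0.0104 with an estimated correlation). Fibroblast markers were higher in 2 of 3 cases with 1 lower in PC9 (fry down, adjusted p = 0.640, with a median of 0.20 and a mean of 0.06), and lower in 4 of 5 in HCC4006 (fry adjusted p = 1.35e-09, and 0.0528 with an estimated correlation). For these markers the limits given under DMSO, from the filter and the differing members, hold here too.

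Pro-apoptotic BCL2 family genes were higher in 6 of 10 cases with 2 lower in PC9, and in 3 of 10 with 1 lower in HCC4006 (adjusted p = 0.328 and 0.434 with an estimated correlation). BMF reached 41.9 ± 1.34 FPKM in PC9 YAP1 KO cells against 10.4 ± 0.538 in CTRL cells (log2 1.92, SE 0.069, adjusted p = 1.46e-09), and 157 ± 4.22 against 101 ± 9.86 in HCC4006 (0.64, SE 0.064, adjusted p = 1.00e-05). BCL2L11 was higher by 0.59 and 0.50. PMAIP1, which encodes the BH3-only protein NOXA, was 0.89 higher in PC9 and had 0.15 in HCC4006 (adjusted p = 0.125). BCL2L1 changed by -0.49 and -0.70. Genes lower in both lines by 2-fold or more also included the receptor gene EPHA2 (-1.64 and -1.75), the adhesion molecule gene ICAM1 (-1.26 and -1.56), SCEL (-1.36 and -1.58) and TMEM255A (-1.70 and -1.31). Higher in both were BAMBI (1.71 and 1.02), C8orf4 (1.54 and 1.42), the protease gene HPN (1.11 and 1.11) and RND1 (1.83 and 1.05). RRAD, a small GTPase, changed by 2.02 in PC9 and -1.66 in HCC4006. Under OT 3609 genes were higher and 3199 lower in PC9 YAP1 KO cells (82 and 125 at least 2-fold), and 3561 and 2155 in HCC4006 (62 and 199). At a pseudocount of 0.1 the 2-fold counts were 223 and 227 and 153 and 373. With median-of-ratios scaling the HCC4006 split was 2679 higher to 2639 lower, 50.4% in place of 62.3%, and in PC9 the majority turned, with 3061 higher to 3635 lower (45.7%), against 4314 to 2746 (61.1%) with each library rescaled to the same sum. Adjusted over the list alone, counts changed for focal adhesion genes (25 lower), Hippo components (12 lower), S-phase genes (13 lower) and fibroblast markers (1 higher) in HCC4006, and for no other list named here.

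The fourth comparison asked whether the response to OT itself differed by genotype, as the interaction of genotype and treatment. The change of YAP/TEAD target genes with OT lay mostly lower in YAP1 KO than in CTRL cells: 14 of 22 had a lower interaction and 1 a higher one in PC9, and 16 of 21 a lower one in HCC4006 (adjusted p = 1.36e-06 and 1.67e-08, and 0.0540 and 0.0104 with an estimated correlation). CTGF, which had risen with OT in CTRL cells, changed by -0.47 in PC9 and -1.87 in HCC4006 YAP1 KO cells, an interaction of -1.46 and -2.81 (adjusted p = 9.53e-06 and 9.66e-09). CYR61 changed by -0.94 and -1.51 with OT in YAP1 KO cells, with an interaction of -1.60 and -2.10. Genes of the list that fell in CTRL cells could fall further, as ANKRD1 did in PC9, by -2.00 in CTRL and -2.60 in YAP1 KO cells (interaction -0.60, adjusted p = 0.00657). Other interactions below 0 in both lines were those of TGFB2 (-0.88 and -1.56), F3 (-0.65 and -1.71), the WNT antagonist DKK1 (-1.19 and -1.65), EPHA2 (-1.17 and -1.66), FJX1 (-1.17 and -1.18), the receptor AXL (-0.62 and -1.11) and the EMT transcription factor SNAI2 (-0.87 and -0.68). Focal adhesion genes had a lower interaction in 15 of 29 and 20 of 30 cases (adjusted p = 0.213 and 0.0528 with an estimated correlation).

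**Figure D4:**
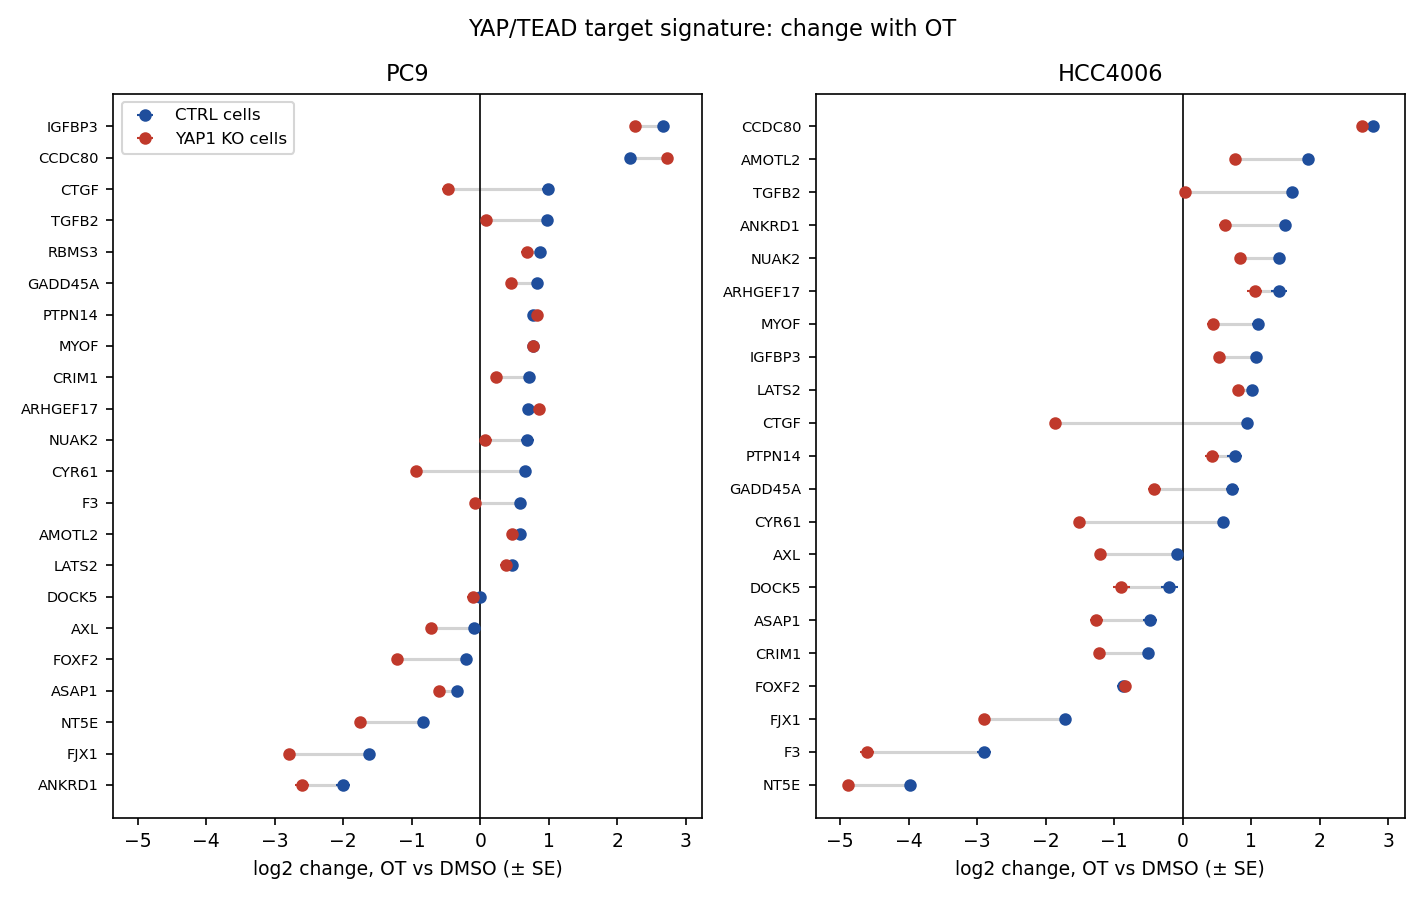
Log2 change with OT against DMSO for each measured gene of the YAP/TEAD target signature, in CTRL cells (blue) and YAP1 KO cells (red), with bars for the SE, in PC9 (left) and HCC4006 (right). For 14 of 22 genes in PC9 and 16 of 21 in HCC4006 the change in YAP1 KO cells lay below that in CTRL cells by the interaction test.

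BMF rose by 4.06 in PC9 and 4.09 in HCC4006 YAP1 KO cells, and its interaction was 1.97 (SE 0.097, adjusted p = 1.91e-07) and 0.76 (SE 0.090, adjusted p = 0.000132). BCL2L11 had an interaction of 0.71 and 0.55 and BCL2L1 one of -0.62 and -0.71. Pro-apoptotic genes had a higher interaction in 4 of 10 and 2 of 10 cases, with 1 lower in each line (adjusted p = 0.194 and 0.341 with an estimated correlation). Interactions above 0 in both lines included the death ligand gene TNFSF10 (0.92 and 1.00), the water channel AQP3 (1.39 and 1.92), the kinase DAPK2 (1.46 and 0.90), RND1 (1.60 and 1.09) and the stress gene DDIT4 (1.05 and 0.64). S-phase genes fell further in PC9 YAP1 KO cells, 29 of 30 (adjusted p = 0.0121 with an estimated correlation), and 7 of 30 had a lower and 2 a higher interaction in HCC4006 (adjusted p = 0.227 with an estimated correlation), with TYMS at -1.27 and -0.76. G2/M genes had a lower interaction in 23 of 30 cases in each line (adjusted p = 0.0274 and 0.0933 with an estimated correlation), with CDK1 at -0.73 and -0.76. Interferon response genes had a higher interaction in 5 of 26 and 14 of 30 cases and lysosome genes in 13 of 27 and 5 of 27. With an estimated correlation the adjusted p was 0.204 and 0.106 for interferon genes and 0.0743 and 0.194 for lysosome genes.

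In YAP1 KO cells OT raised 4682 and lowered 5255 genes in PC9 (742 and 993 at least 2-fold), and raised 6081 and lowered 4781 in HCC4006 (1919 and 1441). At a pseudocount of 0.1 these 2-fold counts were 1137 and 1350 in PC9 and 2707 and 1777 in HCC4006. With each library rescaled to the same sum the PC9 majority turned, to 5466 raised and 4456 lowered (1038 and 970 at least 2-fold), and HCC4006 had 7057 and 3806, while median-of-ratios scaling gave nearly even splits of 5014 and 4946 and of 5451 and 5390. The highest responses there included MUC20 (3.98 and 4.69), and the lowest E2F1 (-3.54 and -3.58). Across genes, which are not independent replicates, the OT response in CTRL cells correlated with that in YAP1 KO cells at r = 0.872 in PC9 and 0.927 in HCC4006. The interaction was above 0 for 1673 and below 0 for 1750 genes in PC9 (35 and 54 beyond 2-fold), and for 1371 and 1073 in HCC4006 (51 and 97). At a pseudocount of 0.1 the counts beyond 2-fold were 78 and 117 and 148 and 198. With each library rescaled to the same sum, PC9 had 2085 above and 1352 below, a share of 60.7% in place of 48.9%, whereas median-of-ratios scaling gave 1442 above and 2057 below (41.2%). In HCC4006 the majority turned under median-of-ratios scaling, with 1073 above and 1212 below (47.0% in place of 56.1%). Adjusted over the list alone, 30 S-phase genes in PC9 and 10 in HCC4006 had a lower interaction, as did 28 G2/M and 22 focal adhesion genes in HCC4006, where 1 focal adhesion, 15 interferon and 6 lysosome genes had a higher one. In PC9 5 pro-apoptotic genes then had a higher interaction, and YAP/TEAD counts were the same.

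Because choosing genes by their response in CTRL cells and testing the interaction on the same libraries would bias it, the genes were chosen in one line and tested in the other. Of 1198 genes that fell at least 2-fold with OT in HCC4006 CTRL cells, 56.4% had an interaction below 0 in PC9, against 9.35% of other genes, and of 1276 that rose, 39.2% had one above 0, against 10.3% (adjusted p = 0.000205 and 0.000645 with an estimated correlation). Their median OT change in PC9 was -0.87 in CTRL and -1.11 in YAP1 KO cells for the genes that fell, and 0.60 and 0.79 for those that rose. Chosen in PC9 and tested in HCC4006, 24.4% of 562 genes that fell had an interaction below 0, against 7.46% of other genes (adjusted p = 0.0048 with an estimated correlation). Their median OT change in HCC4006 was -1.83 in CTRL and -1.93 in YAP1 KO cells. Of 367 genes that rose in PC9, 25.3% had a higher and 21.5% a lower interaction in HCC4006, and their median OT change there was 1.49 in CTRL and 1.54 in YAP1 KO cells. For the interaction that set passed the fry test (up, adjusted p = 0.0147), but not with an estimated correlation (adjusted p = 0.730), nor without replicate 1 of PC9 CTRL DMSO (0.0620) or replicate 1 of HCC4006 YAP1 KO OT (0.0594). Under OT itself the same set pointed down in HCC4006 YAP1 KO against CTRL cells, with 132 genes lower and 118 higher (fry adjusted p = 1.71e-06, and 0.0345 with an estimated correlation), with a median of -0.000374.

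The lines shared much of the response to OT and little of the YAP1 KO difference under DMSO. Among 11845 genes tested in both, 266 were at least 2-fold higher and 454 lower with OT in CTRL cells of both, where independent lists would share 39.5 and 56.8. Under DMSO, 284 genes were higher and 306 lower in YAP1 KO cells of both lines at any size (220 and 190 for independent lists), and YAP1 was the 1 gene lower by 2-fold or more in both. Without replicate 1 or 2 of HCC4006 YAP1 KO DMSO the 284 became 178 in each case, and without replicate 1 the 306 became 203. The count of 1 became 2 without HCC4006 CTRL DMSO replicate 1, CTRL OT replicate 1 or 3, YAP1 KO DMSO replicate 1 or 3, or YAP1 KO OT replicate 3. Under OT, 4 genes were at least 2-fold higher and 16 lower in YAP1 KO cells of both (0.258 and 1.28 for independent lists), and for the interaction the counts were 2, AQP3 and RND1, and 10 (0.0750 and 0.306). Without replicate 1 of HCC4006 CTRL DMSO the 2 became 1. Across genes the 2 lines' changes correlated at r = 0.713 for OT in CTRL cells, 0.0516 for YAP1 KO under DMSO, 0.229 for YAP1 KO under OT and 0.216 for the interaction. Without rows of short RNAs these were 0.759, 0.0660, 0.283 and 0.360. Tested directly, the change differed between lines by more than 1 on the log2 scale for 510, 36, 88 and 1 genes. At a pseudocount of 0.1 these counts were 734, 78, 138 and 0 (71 for the last at an unadjusted limma treat p under 0.05). At a pseudocount of 1 the 1 gene was GPR176, named after its value was seen, with an interaction of 0.89 in PC9 and -1.26 in HCC4006. That count was 0 without PC9 CTRL DMSO replicate 1 or 2, PC9 CTRL OT replicate 2 or 3, PC9 YAP1 KO DMSO replicate 3, any 1 of the PC9 YAP1 KO OT libraries, HCC4006 YAP1 KO DMSO replicate 3 or HCC4006 YAP1 KO OT replicate 3, where limma's test against a difference of 1 had 37 to 44 genes at an unadjusted p under 0.05. It was 2 without PC9 CTRL OT replicate 1 or replicate 2 of HCC4006 CTRL OT, YAP1 KO DMSO or YAP1 KO OT, and 4 without HCC4006 CTRL DMSO replicate 2.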

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

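Of the tests weighed here, those of a trait of the PC9 YAP1 KO cells alone, of noise with rows of short RNAs left out, and of a trait of each YAP1 KO population were chosen after the result was seen. Single libraries within the groups of 3 were not tested for lying apart. HCC4006 CTRL OT replicate 1 had the lowest FPKM sum (507120) and the highest relative depth (1.42), and without it 1790 and 1556 genes were higher and lower in HCC4006 YAP1 KO cells under DMSO, in place of 1206 and 1134.

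The lines responded to OT with changes that differed by more than 1 on the log2 scale in 510 genes (limma treat, adjusted over 11845 genes). The following values are HCC4006 minus PC9, with adjusted p from 1.13e-14 for MET to 0.0204 for BBC3. Among named proliferation and MAPK genes, those that fell further in HCC4006 were these: CDK1 differed by -2.92, TOP2A by -2.89, AURKB by -2.81, RRM2 by -2.52, CCND1 by -2.48, MKI67 by -1.83, CDC6 by -1.63, DUSP6 by -2.93 and PHLDA1 by -1.73. The log2(FPKM + 1) scale understates falls of low genes, and whether low levels in PC9 limited these falls was not tested. Among YAP/TEAD targets ANKRD1 differed by 3.50, IGFBP3 by -1.58 and NT5E by -3.14, and the YAP1 paralog WWTR1, which encodes TAZ, differed by -1.45. The stress response genes CHAC1, PHGDH and ATF3 differed by 3.23, 2.18 and 1.47, and the pro-apoptotic BBC3 by 1.69. Metabolic genes differed by -2.26 (MSMO1) and -1.24 (LDHA). The remaining named genes were VTCN1 (2.60), CTSF (1.71), MX2 (2.21), HOPX (1.84), LOX (2.53), MET (-2.95) and KRT18 (-2.45).

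The YAP1 KO difference differed between lines by more than 1 in 36 genes under DMSO and 88 under OT (78 and 138 at a pseudocount of 0.1), and the interaction in 1, GPR176, named after its value was seen. Named genes had adjusted p from 2.67e-10 to 0.00261 under DMSO and from 8.34e-11 to 0.0469 under OT. Under DMSO the matrix and cytoskeleton genes VIM, COL6A2 and SPARC differed by -1.96, -2.17 and -1.87, ANKRD1 by -1.82 and SH3BGRL by -2.45, and the sterol gene INSIG1 by 1.71. Under OT the YAP/TEAD targets CTGF, CYR61, F3 and ANKRD1 differed by -2.36, -1.58, -1.45 and -2.10. MYL9, SPARC, COL6A2 and LOX differed by -2.07, -1.80, -2.14 and -1.70, INSIG1 by 1.78 and RRAD by -3.69.

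The first pattern is that in PC9 OT moved its target genes further in YAP1 KO than in CTRL cells, with a median interaction of 0.21 for genes that rose 2-fold in HCC4006 and -0.25 for those that fell. A scaling difference between libraries is argued against, because over 3 other scalings the medians were 0.189 or higher for the first set and -0.227 or lower for the second. A trait of the PC9 YAP1 KO cells alone is argued against for the genes that fell, since the genes chosen in PC9 also had an interaction below 0 in HCC4006 (adjusted p = 0.0048 with an estimated correlation), but for those that rose it stays open (adjusted p = 0.730). In HCC4006 the genes that rose had medians of 1.49 in CTRL and 1.54 in YAP1 KO cells (1.84 and 1.83 with libraries rescaled to the same sum), 58% were larger in YAP1 KO cells, and under OT the set pointed down in YAP1 KO against CTRL cells (adjusted p = 0.0345 with an estimated correlation), so a larger rise is not shown in that line. A stronger fall after YAP1 loss is a hypothesis that may fit these values, and with 1 YAP1 KO population per line a trait that both populations acquired was not tested.

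The second pattern is that YAP1 KO differences under DMSO were nearly unrelated between the lines (r = 0.0516 across genes). Noise between libraries would give low correlations within a line too, and the lowest between independent pairs of 1 line was 0.163, near the highest of 0.136 between lines, which leaves noise open when all genes are used. Without rows of short RNAs the lowest within a line was 0.480 and the highest between lines 0.107, which argues against noise. A trait of each YAP1 KO population that is unrelated to YAP1 may account for the pattern and cannot be told apart from a line-specific effect of YAP1, since each line has 1 such population. Over 21 YAP/TEAD target genes the correlation between lines was 0.0926 under DMSO and 0.596 under OT.

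The third pattern is that rows of short RNAs were among the largest changes in some comparisons: in PC9 and HCC4006 they were 14 and 6 of the top 20 for OT in CTRL cells, 6 and 3 for YAP1 KO under DMSO, 0 and 6 for YAP1 KO under OT, and 4 and 1 for the interaction. Their residual SD was 22.1 times that of other rows of the same mean in PC9 (median of 119 rows) and 18.4 times in HCC4006 (129 rows). That is consistent with imprecise FPKM of rows much shorter than a sequenced fragment. No biological explanation was tested.

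Other splits of the libraries were also counted. The 6 libraries of a pair of groups make 10 splits, too few for a share under 0.05, and 1 of 10, the real one, gave as many calls in each of the 8 comparisons. Every other split mixes libraries of the groups compared, which puts their difference into the residual spread. Low numbers from those splits follow from this and lend no support to the real ones. The real numbers were 9256, 9937, 5057 and 6808 genes in PC9 for OT in CTRL, OT in YAP1 KO, YAP1 KO under DMSO and YAP1 KO under OT, and the highest of other splits were 1, 1, 1 and 2. In HCC4006 they were 10700, 10862, 2340 and 5716, against 1, 2, 1 and 2. For OT in HCC4006 CTRL cells, whose replicate numbers met the rule for pairing, the splits other than the real one that also part all 3 pairs are among these and gave at most 1 gene. For the interaction 3 of 100 splits of the genotypes within treatments gave as many genes in PC9 (3423, highest other 7275) and 6 of 100 in HCC4006 (2444, highest other 3824). The larger splits point to a structure of the samples: all 2 others in PC9 and all 5 in HCC4006 that reached the real number parted the libraries by their true genotypes under at least 1 treatment, and so carry the genotype difference itself. Among the 80 and 77 that did so under neither, the highest were 2 and 3 genes, and there the mixing likewise raises the residual spread. Splitting the genotypes also breaks the genotype difference that both treatments share, so the shares do not decide on the interaction by itself. In HCC4006 the share of all splits is over 0.05 only through those 5. For differences between lines as many genes came from 3 of 100 splits for OT (7722, highest other 8476), 1 for YAP1 KO under DMSO (3557, 2579), 2 for YAP1 KO under OT (5037, 6610) and 4 for the interaction (1594, 3263). Such splits also break the effect within each line, so their shares cannot show that the lines differ.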

How the results depend on the processing

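The alternatives that leave out a library for line differences, gene sets of one line tested in the other and overlaps, and those without rows of short RNAs, also for correlations of the lines, were chosen after seeing the data. Of 420 results for named genes, 381 kept their side of the threshold, and where called their direction, in every setting that kept the gene. The direction of genes not called was not compared. Of the others, 3 took the other sign, whether or not they passed there, 25 lost their call in at least 1 setting and 13 gained one, and 2 of these count in a pair of the classes. With the filter at FPKM of 5, 394 results were the same, 1 gained a call and the rest were not tested. Without rows of short RNAs, all 40 counts of genes per comparison were within 1.5 times, and the correlation of the lines across genes moved to 0.759 for OT in CTRL cells, 0.283 for YAP1 KO under OT and 0.360 for the interaction. Replicate numbers met the rule for pairing in 1 of 12 pairs of groups, HCC4006 CTRL cells under DMSO and OT, where the block changed no call of a list or named gene and gave 5912 higher and 4825 lower genes. Values as far below 0 were found for PC9 CTRL DMSO with YAP1 KO OT (-0.16, -0.264 and -0.143), so real pairing is not shown. Over all pairs of groups, 3 of 18 pairs in PC9 and 5 of 18 in HCC4006 had a correlation of deviations over 0.1 (from -0.264 to 0.161 and from -0.150 to 0.236), and 3 of 12 and 5 of 12 libraries correlated best with their own number. With the replicate block all 40 counts stayed within 1.5 times, and of the list results 290 were the same, 4 lost and 5 gained a call, and 1 reversed (alveolar type 1 genes for OT in HCC4006 YAP1 KO cells, adjusted p = 0.0155). By camera, which compares a list with the other genes, 208 list results called by fry did not pass and 86 were the same. It reversed 6: AP-1 subunits for OT in PC9 CTRL (adjusted p = 0.952), PC9 YAP1 KO (0.960) and HCC4006 YAP1 KO cells (0.906), neuroendocrine markers in PC9 CTRL (0.892) and YAP1 KO cells (0.883), and alveolar type 1 genes in HCC4006 CTRL cells (0.901). Absolute depth is unknown, and low genes are those whose values depend most on the pseudocount.

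Counts of 2-fold genes depend on the pseudocount. At 0.1, PC9 had 743 higher and 928 lower for OT in CTRL, 1137 higher for OT in YAP1 KO, 160 and 140 for YAP1 KO under DMSO, 223 and 227 under OT, and 78 and 117 for the interaction. HCC4006 then had 2417 higher for OT in CTRL, 32 and 169 for YAP1 KO under DMSO, 153 and 373 under OT, and 148 and 198 for the interaction, and the genes differing between lines by more than 2-fold numbered 78, 138 and 0 for YAP1 KO under DMSO, under OT and the interaction (71 for the last at an unadjusted limma treat p under 0.05). At 0.01 the PC9 counts were 783, 979, 1196, 174, 150, 257, 248, 80 and 128 in the same order, and those of HCC4006 2507, 44, 216, 152, 414, 152 and 218. With FPKM of 5 or more, where fewer genes are tested, PC9 had 35 and 53 genes 2-fold higher in YAP1 KO cells under DMSO and OT, and HCC4006 3917 and 4048 genes higher with OT in CTRL and YAP1 KO cells. With each library rescaled to the same sum, 2-fold higher genes were 133 for YAP1 KO under OT in PC9, and 2611, 12 and 81 for OT in CTRL, YAP1 KO under DMSO and the interaction in HCC4006. Robust empirical Bayes gave 1 for YAP1 KO under DMSO in HCC4006. Median-of-ratios scaling gave 2 genes differing between lines in the interaction, YAP1 levels of 42.2, 35.2 and 5.78 in PC9 CTRL DMSO, PC9 CTRL OT and HCC4006 YAP1 KO OT, and reversed oxidative phosphorylation for OT in PC9 CTRL cells (adjusted p = 0.0199). In the PC9 interaction the log2 change of DUSP6 took the other sign at a pseudocount of 0.01 (0.0868, limma adjusted p = 0.968). Under quantile normalization the log2 changes of MCL1 (0.0942, adjusted p = 0.0154) and AXL (0.00597, adjusted p = 0.894) did so for OT in PC9 CTRL cells. Of these genes only MCL1 passed in the new direction. Genes that rose with OT in PC9, tested for the interaction in HCC4006, had an adjusted p of 0.730 with an estimated correlation and 0.555, reversed, when chosen at a log2 change of 2. FPKM sums were lower in every OT library than in any DMSO library of its line, so rescaling to the same sum raises OT against DMSO values. The sums were 566982 to 593526 against 604392 to 620813 in PC9, and 507120 to 574160 against 621936 to 660459 in HCC4006. In PC9 the rows of MIR1244-1 and MIR1244-2 held at most 3.629% of the sum under OT and at least 5.264% under DMSO. In HCC4006 these shares were at most 3.807% and at least 5.816%. The lower sums, and so the shifts under rescaling to the same sum, thus rest in part on these rows. Rescaling with them left out was not tested. Except for the stricter filter, other causes were not tested.

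At a log2 change of 1 in both lines, overlaps were 266 higher and 454 lower for OT in CTRL, 471 and 712 for OT in YAP1 KO, 0 (also 0 at an unadjusted limma p under 0.05 in each line) and 1 for YAP1 KO under DMSO, 4 and 16 under OT and 2 and 10 for the interaction. Leaving out each library in turn, results that changed ranged from 681 (without YAP1 KO DMSO replicate 1) to 1790 (without CTRL OT replicate 1) genes higher in HCC4006 YAP1 KO cells under DMSO, with 2 (without YAP1 KO OT replicate 1) to 6 (without YAP1 KO DMSO replicate 3) of them 2-fold, 0 to 4 (without HCC4006 CTRL DMSO replicate 2) genes differing between lines in the interaction, with 37 to 44 at an unadjusted limma treat p under 0.05 where it was 0, and an adjusted p of 0.0018 (without HCC4006 CTRL OT replicate 2) to 0.0620 (without PC9 CTRL DMSO replicate 1) for the genes that rose in PC9. Overlaps for YAP1 KO under DMSO ranged from 178 to 405 higher and 203 to 406 lower (lowest without HCC4006 YAP1 KO DMSO replicate 1, highest without HCC4006 CTRL OT replicate 1) and 1 to 2 at least 2-fold lower, and for the interaction from 1 to 3 at least 2-fold higher.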

Other observations

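No test in this part was added after the result was seen. Several gene groups not described so far moved with OT in CTRL cells, and changes below are given for PC9 and then HCC4006. Replication-dependent histone genes rose in 8 of 9 and 7 of 8 cases (fry adjusted p = 1.5e-08 and 1.1e-06, and 0.0487 and 0.325 with an estimated correlation), with HIST1H2BD at 2.33 and 2.05. The libraries were made with an mRNA kit, and 1 value per gene does not show which form of these transcripts was measured. A rise of S-phase histone expression is therefore not shown. MHC class I genes rose in 5 of 5 and 4 of 5 cases, with 1 lower in HCC4006 (fry adjusted p = 1.46e-08 and 9.83e-10, and 0.0929 and 0.257 with an estimated correlation). Secreted genes of senescent cells fell in 8 of 11 and 12 of 17 cases and rose in 3 of each (fry adjusted p = 2.48e-09 and 1.25e-07, and 0.328 and 0.238 with an estimated correlation). Integrated stress and unfolded protein response genes were lower in 15 of 24 cases and higher in 9 in PC9, and higher in 17 of 24 and lower in 4 in HCC4006 (fry adjusted p = 1.53e-06 and 1.56e-07, and 0.771 and 0.442 with an estimated correlation). Among them the glutathione-degrading enzyme CHAC1 changed by -0.50 and 2.73, and PHGDH, of serine synthesis, by -0.91 and 1.27. Nuclear-encoded oxidative phosphorylation genes fell in 22 of 25 cases in HCC4006 (fry adjusted p = 5.37e-05, and 0.434 with an estimated correlation). In PC9 8 of them rose and 9 fell, with a median of 0.04 and a mean of -0.01, and the list did not pass (fry down, adjusted p = 0.282), but pointed up under median-of-ratios scaling (adjusted p = 0.0199). Cytosolic ribosomal protein genes rose in 11 of 32 cases and fell in 2 in PC9, and rose in 3 and fell in 22 of 32 in HCC4006 (fry adjusted p = 0.0279 and 0.0425, and 0.828 and 0.754 with an estimated correlation). Adjusted over the list alone those PC9 counts were 8 and 1, and all other counts of this part were the same.

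Of p53 target genes 8 rose and 9 fell of 21 in PC9, and 14 rose and 3 fell of 22 in HCC4006 (fry up, adjusted p = 0.0153 and 0.000135, and 0.851 and 0.691 with an estimated correlation). AP-1 subunits rose in 5 and fell in 4 of 10 cases in PC9, and rose in 6 and fell in 3 of 11 in HCC4006 (fry adjusted p = 7.98e-05 and 4.16e-07, and 0.952 and 0.600 with an estimated correlation). In PC9 their median was 0.07, their mean -0.34, and fry pointed down. ERBB ligands and receptor tyrosine kinases fell in 7 of 13 and rose in 5 in PC9, and fell in 8 of 17 and rose in 7 in HCC4006 (fry down, adjusted p = 0.000103 and 8.33e-05, and 0.946 and 0.754 with an estimated correlation), with the EGFR ligand AREG at -0.98 and -1.93. The PC9 call was lost under median-of-ratios scaling (adjusted p = 0.284).

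Alveolar type 1 genes rose in 4 of 6 and fell in 2 in PC9, and rose in 2 and fell in 3 of 7 in HCC4006 (fry up, adjusted p = 1.54e-08 and 3.21e-06, and 0.348 and 0.901 with an estimated correlation), with HOPX at 1.71 and 3.55. In HCC4006 the median of that list was -0.15 and its mean 0.59. Alveolar type 2 genes rose in 1 and fell in 2 of 4 in PC9 (fry down, adjusted p = 2.34e-07, and 0.834 with an estimated correlation), a call lost at a pseudocount of 0.1 (adjusted p = 0.276). They rose in 6 and fell in 2 of 9 in HCC4006 (fry up, adjusted p = 1.49e-07, and 0.356 with an estimated correlation). Of 3 measured anti-apoptotic BCL2 family genes 1 rose and 1 fell in PC9 (fry down, adjusted p = 5.11e-05, and 0.892 with an estimated correlation), and 2 rose and 1 fell in HCC4006, where the median was 0.17, the mean -0.13 and the fry adjusted p 0.285 (down, and 0.0132 under median-of-ratios scaling). Fibroblast markers rose in 3 of 3 and 4 of 5 cases, with 1 lower in HCC4006 (fry adjusted p = 2.16e-07 and 4.39e-10, and 0.194 and 0.261 with an estimated correlation). Leukocyte and endothelial markers, measured in HCC4006 only, rose in 4 of 4 and 2 of 2 cases (fry adjusted p = 7.87e-08 and 8.23e-08, and 0.323 and 0.397 with an estimated correlation). The filter keeps a gene with FPKM of at least 1 in 3 libraries, the size of 1 group. A marker near 0 under DMSO could thus enter only by rising with OT, so the counts and tests of fibroblast, leukocyte and endothelial markers cannot show a response. Neuroendocrine markers rose in 2 and fell in 1 of 3 in PC9, with a median of 0.17 and a mean of -0.29, and fell in 2 of 4 in HCC4006 (fry down, adjusted p = 0.000382 and 5.09e-05, and 0.892 and 0.482 with an estimated correlation).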
